A study of Glycine max with 42 samples.

How the data were processed

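Gene expression was measured in root hair cells of soybean (Glycine max) cultivar Williams 82. Per the labels, seeds germinated in the dark on agar without nitrogen, and seedlings were sprayed after 3 days with a suspension of Bradyrhizobium japonicum strain USDA110, a bacterium that forms nitrogen-fixing nodules on soybean, or with water (mock inoculation). Root hair cells were isolated 6, 12, 18, 24, 36 or 48 h later, and biotin-labelled cRNA made from their total RNA was hybridised to Affymetrix soybean arrays. The 42 arrays form 12 groups, an inoculated and a mock group at each of the 6 times. Each group had 4 arrays at 6, 12 and 18 h and 3 arrays at 24, 36 and 48 h, and the series text describes them as independent biological replicates.

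The values used were those the authors deposited, log2 expression values per probe set made with GCRMA, per the labels' processing notes. A probe set is the group of short probes that measures 1 transcript. GCRMA estimates background from probe sequence, normalises between arrays and summarises the probes of each probe set. Its version and settings were not given in the sources used here. The table has 61170 rows, of which 37641 hold values on every array and 23529 are blank on every array. Of the rows with values, 37593 were soybean transcript probe sets and 48 were ribosomal RNA probe sets, which were kept apart. The planned test of probe sets of other organisms on the array was not run, because their rows are blank in the table. Array medians lay between 6.84 and 6.97 on the 24 arrays of 6 to 18 h and between 5.20 and 5.77 on the 18 arrays of 24 to 48 h, so these sets look normalised separately. No level at 6, 12 or 18 h was therefore set against a level at 24, 36 or 48 h, whereas each inoculated group and its mock group lie in 1 set. GCRMA values near background depend on its background model, so a fold change against a group mean under 5 is approximate, and none is given where both group means lie under 5. For arrays, the number of arrays limits the precision, and no counts lie behind the values.

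Genes were taken from the platform annotation. It lists 1 gene for 8677 probe sets (6031 genes), several genes for 370 and no gene for 28546. A symbol other than a locus number was held by 1882 probe sets (1131 genes), and 8652 probe sets had their gene in the RefSeq table of the Glycine_max_v4.0 assembly, which was used for names only. Most soybean probe sets are therefore unnamed here. Where a gene has several probe sets, each was tested, and the gene lists used the probe set with the highest mean over all arrays. Probe sets of a gene disagreed in direction with a called one for WRKY48 at 12 h (log2 change -1.01 against 0.25), PEPC7 at 48 h (1.27 against -0.17) and GDH1 at 18 h (0.73 against -0.63).

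Probe sets with a log2 value above 5 in at least 3 arrays of a group were kept, which left 25711 and removed 11882. The floor of 5 was the fallback fixed in advance for a table without the other organisms' probe sets. One mean per group was fitted to all 42 arrays with limma 3.58.1 in R 4.3.3, giving 30 residual degrees of freedom. Contrasts were tested with limma's moderated test and an intensity trend (eBayes with trend), two-sided. P-values were adjusted by the Benjamini-Hochberg method over the 25711 probe sets of each contrast, at a false discovery rate of 0.05. A probe set past that threshold is called. The contrasts were inoculated against mock at each of the 6 times, their average, the moderated F test of whether the 6 contrasts differ, and mock 18 h against 6 h and mock 48 h against 24 h. The spread is thus shared by all groups. Errors of log2 changes are standard errors (SE) and errors of group means are standard deviations (SD). The contrasts, filter, threshold, alternatives and rule for named genes were chosen before the data were examined.

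The series gives inoculated and mock arrays of a time the same replicate numbers, so it was checked whether same-numbered arrays deviate together from their group means. Over all tested probe sets the correlation of these deviations was above 0.1 for each pair at 6 h (0.216 to 0.569), 12 h (0.291 to 0.673), 24 h (0.374 to 0.861), 36 h (0.195 to 0.939) and 48 h (0.423 to 0.906), and for each pair of mock 24 and 48 h arrays (0.573 to 0.804). Of the inoculated arrays, replicates 3 and 4 at 6 h and replicate 1 at 12 and 48 h correlated more with a mock array of another number. At 6 h replicate 4 had 0.216 with its own number and a median of 0.21 with the others, so the pairing is less clear there. The pairing at 6, 12, 24, 36 and 48 h comes from these correlations alone, as no label ties a number to a day or batch. There the fit with time by replicate number as a block is given beside a result where it changes a call or moves a count by over 1.5 times. The log2 change of a contrast is the same in both fits. Each SE printed is that of the fit without the block, also where it stands beside an adjusted p with the block. At 18 h the pair numbered 3 had -0.168 and the others 0.123 to 0.424. For mock 6 and 18 h the pair numbered 3 had -0.391 and the others 0.187 to 0.653. As not every pair was above 0.1, those arrays were not treated as paired, but a pairing of some of them is not excluded.

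Named genes had a gene symbol, passed the threshold at their time, had groups that do not overlap and were the 12 largest increases and 8 largest decreases of a time (8 and 6 for the average and the mock contrasts), with up to 4 called members of each gene list at the time with most calls in it, or the member with the smallest p where none was called. ENOD40B, IFS1, IFS2 and PR-10 (SAM22) were named whatever their result, whereas NIN, NFR1, NFR5, NSP1 and NSP2 had no probe set under those symbols and ENOD93 did not pass the floor. The same rule applied to the block fit, with each pair changed in the same direction, was added after seeing the data. Named genes called with the block alone were refitted with each pair of their time left out, which was also added then. Gene lists were planned by subject. They were redrawn by gene symbol after the annotation was seen to hold no descriptions and before any expression test, and 27 lists with at least 5 tested genes were used. No list of root hair, endodermis or root cap markers could be drawn from the symbols; markers of green tissue, phloem and seed storage stand for the other tissues a preparation could hold. Each list was tested in 9 contrasts with camera at a preset correlation of 0.01 and with an estimated correlation, and with fry. The p-values were adjusted over all lists and the 6 times together. For the average and each mock contrast they were adjusted over the lists of that contrast alone. Members were also counted after adjustment over the list alone.

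The pipeline was tested on simulated data for the 25711 probe sets, with 100 changed by 1 and 100 by 2 on the log2 scale and noise drawn independently. At 6 h the fit found 19% of the changes of 1 and 60% of the changes of 2 with 4 false calls, at 12 h 25% and 61% with 3, at 18 h 27% and 60% with 6, at 24 h 19% and 52% with 5, at 36 h 16% and 49% with 5, and at 48 h 15% and 48% with 5. With noise shared within pairs, the block fit found 76% and 92% at 6 h with 10 false calls, 74% and 88% at 12 h with 9, 70% and 89% at 18 h with 8, 54% and 82% at 24 h with 7, 63% and 84% at 36 h with 12, and 63% and 83% at 48 h with 6. The fit without the block then found 24% and 56% at 6 h, 24% and 51% at 12 h, 24% and 50% at 18 h, 13% and 41% at 24 h, 13% and 39% at 36 h and 11% and 44% at 48 h, with 0 false calls. The simulated pairs shared most of their variance, by the same amount at each time and above every pair correlation found at 6, 12 and 18 h. The gain with the block at those times is thus that of a stronger pairing than the arrays show. For the lists, 1 simulated list was raised at each of the 6 times and found at 6 of them. None of the unchanged combinations of list and time was called (0 of 156). The noise was independent between probe sets, so this does not test camera on lists whose genes correlate. Nor does it test the false calls of either fit where many probe sets vary together. In the data 1 axis held 36.5% of the variance of the deviations from group means at 6 to 18 h. The alternatives tried were no filter and a stricter floor of 6, leaving out probe sets that can cross-hybridise, median centring, quantile normalisation, no intensity trend, array weights, the replicate block, the compared groups alone and each array left out in turn. Others were added after seeing the data.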

Results

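Transcript levels were measured on 42 arrays of soybean root hair cells, the tubular cells of the root surface through which Bradyrhizobium japonicum enters the root. The design asks how these cells respond to the bacterium over 48 h. Inoculated and mock-inoculated cells were compared at 6, 12 and 18 h with 4 arrays per group and at 24, 36 and 48 h with 3 arrays per group. Values are GCRMA log2 expression values, and 25711 probe sets were tested, of which 7224 have 1 gene in the annotation and 1496 carry a gene symbol (956 genes). No level before 24 h was set against one from 24 h on. Within each time the median log2 change over all tested probe sets lay between -0.05 and 0.03.

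**Figure D1:**
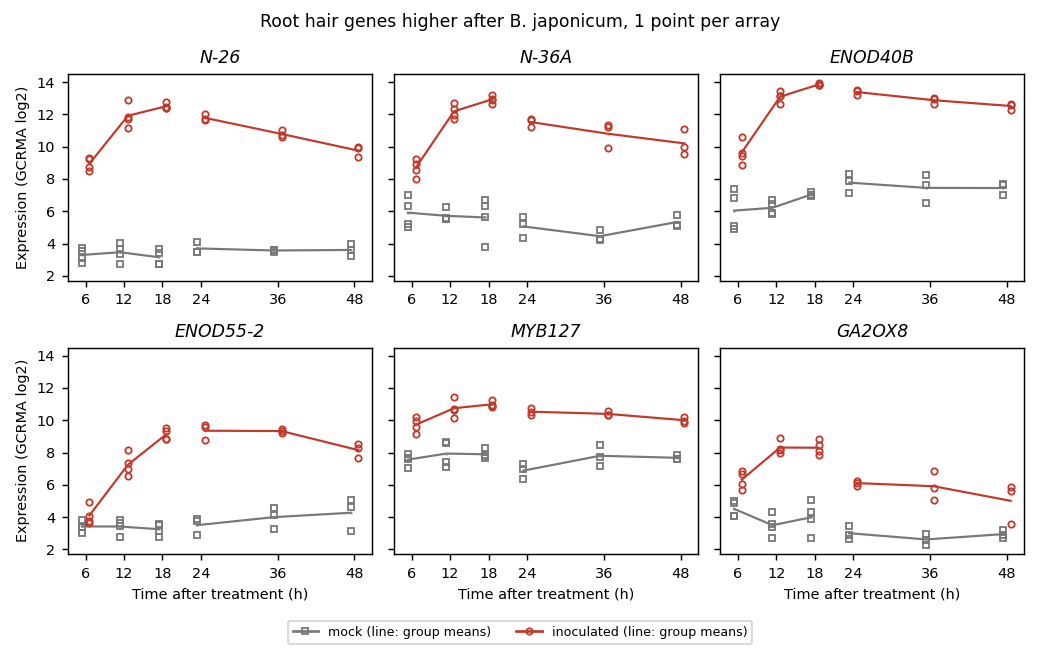
Expression (GCRMA log2, vertical axis) of 6 genes against time after treatment (h, horizontal axis), with 1 point per array, squares for mock, circles for inoculated and lines through the group means within each of the 2 separately normalised sets of arrays. The N-26 means were 8.95 (inoculated) and 3.29 (mock) at 6 h and 12.5 and 3.15 at 18 h, and the ENOD40B means were 13.9 and 7.03 at 18 h and 12.5 and 7.44 at 48 h.

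At 6 h the question was which genes already differed between inoculated and mock root hair cells. Nodulins, genes known for their expression in nodules, led the named genes (n = 4 arrays per group). ENOD55-1 (gene 100784860), an early nodulin, was 76.8-fold higher in inoculated cells (log2 change 6.26 ± 0.84 SE, adjusted p = 1.49e-05), and its mock mean lay under the floor of 5. N-26 (gene 547904), the channel protein nodulin 26 of the membrane around the bacteria in nodules, was 50.5-fold higher (5.66 ± 0.30, adjusted p = 2.14e-15). ENOD40B (gene 547926), a short early nodulin transcript, was 12.2-fold higher (3.60 ± 0.39, adjusted p = 1.83e-07), and N-36A (gene 547771) was 6.81-fold higher (2.77 ± 0.47, adjusted p = 0.000804). Of the 12 nodulins and nodulation regulators tested, these 4 were higher and 0 lower, against 4 higher and 1 lower adjusted over the list alone, and NOD33 (-0.59 ± 0.17, adjusted p = 0.041 with the block) was lower with the block alone, and in 0 of 4 fits with a pair left out. The list differed from other genes by camera with an estimated correlation (adjusted p = 0.00557), but not with the replicate block as well (adjusted p = 0.391 with an estimated correlation).

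Genes of other kinds were also higher at 6 h. HS1pro1 (gene 100174967), a homologue of a nematode resistance gene of beet, was 10.6-fold higher (3.41 ± 0.56, adjusted p = 0.000607), and the pathogenesis-related gene PR1-1 (gene 547547) 7.35-fold (2.88 ± 0.52, adjusted p = 0.002). These were the 2 called members of the 23 defence genes, a list with a median of 0.10 that passed camera (adjusted p = 0.014; 3 higher adjusted over the list alone and 3 with the block). That call was lost with an estimated correlation (adjusted p = 0.604). The transcription factors WRKY12 (2.17 ± 0.43), MYB127 (2.15 ± 0.31), MYB12A (1.59 ± 0.36) and BZIP61 (1.41 ± 0.28) rose, as did FAD2-1A, an oleate desaturase (1.87 ± 0.42), the cytochrome P450 CYP71D8 (1.53 ± 0.32) and the ammonium transporter AMT1.3 (1.53 ± 0.35). Isoflavone synthase makes the isoflavones that legume roots release towards rhizobia. Of its genes, IFS2 rose 1.83-fold (0.88 ± 0.19, adjusted p = 0.0223), whereas IFS1 changed by 0.21 ± 0.11 (adjusted p = 1), and without the block IFS2 was the called member of 35 genes of isoflavonoid and phenylpropanoid synthesis (2 higher and 1 lower adjusted over the list alone, and 4 higher and 1 lower with the block). Probe sets of 4CL1 (-2.13 ± 1.14, adjusted p = 0.0175 with the block), CYP98A2 (-1.55 ± 0.98, adjusted p = 0.0404 with the block) and PAL2.1 (-1.29 ± 0.65, adjusted p = 0.0223 with the block) were lower with the block alone, in 1, 1 and 2 of the 4 fits with a pair left out. Their SEs are those of the fit without the block. With 1 array left out these 3 ran from -2.58 to -1.28, -2.0 to -0.97 and -1.56 to -0.65. Of the 2 probe sets of PR-10, the SAM22 defence gene, the first was called with the block alone (0.65, adjusted p = 0.168 without it and 0.00491 with the block) and the second in neither fit (0.45, adjusted p = 1 and 0.254). The 16 nitrogen uptake genes had a camera adjusted p of 0.0479, and an adjusted p of 0.495 with an estimated correlation. AMT1.3 alone was called, in the 6 h fit and adjusted over the list alone, and 1 was higher and 1 lower with the block. AMT1.3 was called in 0 of the 8 fits with 1 array left out (adjusted p up to 0.159), FAD2-1A in 2, MYB12A and IFS2 in 3. CYP71D8 and WRKY12 were called in 5 and BZIP61 in 6. HS1pro1 (3.11 to 4.19), PR1-1 and MYB127 were called in each of the 8.

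In all, 114 probe sets were called at 6 h, 100 higher and 14 lower in inoculated cells, against 593 higher and 624 lower at an unadjusted p under 0.05. With same-numbered arrays as a block, 563 were called, 254 higher and 309 lower. The balance depends on single pairs, with 132 higher and 42 lower without pair 3, 139 and 50 without pair 4, 195 and 160 without pair 2 and 180 and 398 without pair 1. GA2OX8, a gibberellin-inactivating oxidase (1.81 ± 0.46, adjusted p = 0.0354 with the block), HAD1 (-1.38 ± 0.49, adjusted p = 0.00523 with the block) and ANN11, an annexin (-1.23 ± 0.46, adjusted p = 0.0126 with the block), passed with the block alone, in 0, 3 and 2 of the 4 fits with a pair left out. Without the block the count was 61 without inoculated replicate 1, whose median correlation with the rest of its group was 0.891, and 70 without mock replicate 3.

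At 12 h 3 of the 4 nodulins called at 6 h lay further apart (n = 4 per group). N-26 was 351-fold higher (8.45 ± 0.30, adjusted p = 1.62e-20), ENOD40B 118-fold (6.88 ± 0.39, adjusted p = 6.86e-15) and N-36A 88.6-fold (6.47 ± 0.47, adjusted p = 3.86e-12). ENOD55-1 was 40-fold higher (5.32 ± 0.84, adjusted p = 0.000156, and 4.45 without mock replicate 3), against 6.26 at 6 h. It was not among the named genes whose effect differed between times by the F test. ENOD55-2 (gene 547770) was 14.2-fold higher (3.83 ± 0.38, adjusted p = 1.16e-08), after a change of 0.68 at 6 h that was not called (adjusted p = 1). GA2OX8 (gene 100806026) was 28.1-fold higher (4.81 ± 0.46, adjusted p = 3.76e-09). Of the 12 nodulins, 6 were higher and 1 lower (7 higher and 3 lower adjusted over the list alone, as with the block). The member that fell was NOD33 (-0.84 ± 0.17, adjusted p = 0.0037). The camera adjusted p with an estimated correlation was 0.00831 for the list, and with the block as well it was 0.451.

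Other genes higher at 12 h were HS1pro1 (3.23 ± 0.56), MYB127 (2.81 ± 0.31), AMT1.3 (2.40 ± 0.35), PR1-1 (2.06 ± 0.52) and ITPK4, an inositol phosphate kinase (1.95 ± 0.26). CKX3, a cytokinin oxidase that degrades cytokinins, rose by 1.94 ± 0.46 with both group means under the floor. Smaller increases were those of PHR35 (1.48 ± 0.45), the seed maturation gene PGMPM19 (1.35 ± 0.41), the glutamate dehydrogenase GDH1 (0.77 ± 0.16) and the trypsin inhibitor KTI-2 (0.68 ± 0.21). Among genes lower in inoculated cells, those with groups that do not overlap were led by the kinase WNK13 (-1.61 ± 0.29, adjusted p = 0.0012), the ABC transporter PDR12 (-1.10 ± 0.24, adjusted p = 0.0106), SCA2 (-0.86 ± 0.26, adjusted p = 0.0432), the senescence-associated receptor kinase SARK (-0.82 ± 0.23, adjusted p = 0.0384) and MYB176, a regulator of isoflavonoid genes (-0.79 ± 0.17, adjusted p = 0.0106). Falls with overlapping groups were called for WRKY37 (-2.64 ± 0.77, adjusted p = 0.0424), the cold-inducible zinc finger gene SCOF-1 (-2.31 ± 0.67, adjusted p = 0.0411), the ascorbate oxidase AO (-1.90 ± 0.42, adjusted p = 0.0115) and ERF6, an ethylene response factor (-1.60 ± 0.46, adjusted p = 0.039). Leaving out 1 array in turn, HS1pro1 (2.55 to 3.85), MYB127, AMT1.3, ITPK4, GDH1 and WNK13 were called in each of 8 fits. MYB176 was called in 7, PDR12 in 5, CKX3 and AO in 4, and PR1-1, SCA2 and SARK in 3. PHR35, PGMPM19, KTI-2, WRKY37 (-3.48 to -2.06), SCOF-1 (-2.98 to -1.80) and ERF6 were called in 2 of the 8 (adjusted p up to 0.43).

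Several families of stress-related genes had called members that fell at 12 h. Of 34 glutathione S-transferases, which conjugate glutathione to toxic compounds, 6 were lower and 0 higher, with 2 higher and 8 lower at an unadjusted p under 0.05 and 3 higher and 10 lower with the block. The list did not pass camera (median -0.14, adjusted p = 0.118, and adjusted p = 0.863 with an estimated correlation). The called members included GSTU27 (-1.14 ± 0.31), GSTU26 (-0.75 ± 0.18), GSTL3 (-0.71 ± 0.14) and GSTU42 (-0.51 ± 0.15). Of 42 WRKY factors, 2 were lower and 0 higher, WRKY48 (-1.01 ± 0.31) and WRKY19 (-0.72 ± 0.21), with 4 lower adjusted over the list alone and 12 lower and 1 higher at an unadjusted p under 0.05. With the block, 15 were lower and 1 higher. The WRKY list fell by camera (median -0.38, adjusted p = 0.00806), but not with an estimated correlation (adjusted p = 0.691). Of 19 NAC factors, NAC23 (-1.08 ± 0.32) and NAC018 (-0.78 ± 0.24) fell, 9 were lower with the block, and the list had a median of -0.52 (camera adjusted p = 0.0183, and adjusted p = 0.47 with an estimated correlation). Single members of other lists that fell were the ferritin SFERH-2 (-0.92 ± 0.23), the peroxidase Ep (-0.91 ± 0.27), ANN11 (-0.77 ± 0.23) and the receptor-like kinase CRK84 (-1.20 ± 0.35). GSTL3 was called whichever array was left out, GSTU26 in 4 of 8 fits and the other genes named here in 2 (adjusted p up to 0.411).

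In total 1480 probe sets were called at 12 h, 861 higher and 619 lower. The count with the block was 8072 (4394 higher and 3678 lower, and 2642 to 8926 with a pair left out, with 1678 higher and 1755 lower without pair 4). Without the block it moved by over 1.5 times whichever array was left out, to 162, 327, 157 and 3140 without inoculated replicates 1, 2, 3 and 4 and to 199, 566, 5140 and 137 without mock replicates 1, 2, 3 and 4, and fitted to the 12 h groups alone it was 76.

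**Figure D2:**
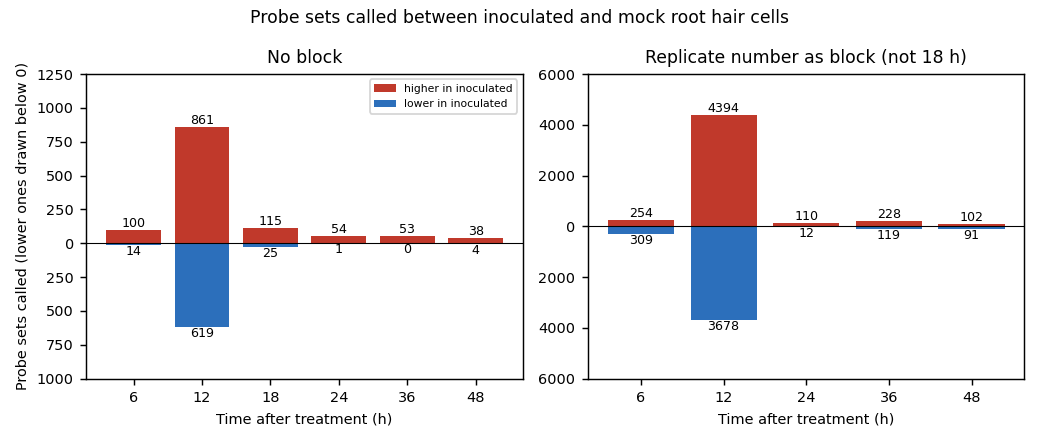
Probe sets called (vertical axis, higher in inoculated cells above 0 and lower ones below) at each time (h, horizontal axis), without a block on the left and with the replicate number as a block on the right, on different scales. Without the block 861 were higher and 619 lower at 12 h, against 53 higher and 0 lower at 36 h, and 18 h is left out on the right because not every pair there deviated together.

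At 18 h the 5 largest changes among the named genes were those of nodulins (n = 4 per group). N-26 was 657-fold higher (9.36 ± 0.30, adjusted p = 6.36e-22), N-36A 160-fold (7.32 ± 0.47, adjusted p = 1.09e-13, and 6.72 without mock replicate 4), ENOD40B 114-fold (6.83 ± 0.39, adjusted p = 6.68e-15) and ENOD55-2 58.9-fold (5.88 ± 0.38, adjusted p = 1.68e-13). N-70 (gene 547772) rose 14.3-fold (3.84 ± 0.33, adjusted p = 3.03e-10) and N-21 (gene 547974) 7.92-fold (2.99 ± 0.30, adjusted p = 1.75e-08). Both had been within 0.02 of 0 at 6 h. ENOD55-1 was 26.4-fold higher (4.72 ± 0.84, adjusted p = 0.00098), against 5.32 at 12 h, and NOD33 had -0.46 and was not called (adjusted p = 0.301). Of the 12 nodulins, 7 were higher and 0 lower (8 higher and 3 lower adjusted over the list alone), with a camera adjusted p of 4.68e-06 with an estimated correlation.

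GA2OX8 (4.32 ± 0.46), HS1pro1 (3.70 ± 0.56), MYB127 (3.10 ± 0.31), AMT1.3 (3.06 ± 0.35) and CKX3 (2.20 ± 0.46) also rose at 18 h. GA2OX8 was the called member of 19 gibberellin and GASA genes, whose median was 0.30 (camera adjusted p = 0.00118, and adjusted p = 0.632 with an estimated correlation; 2 higher adjusted over the list alone) and -0.01 without mock replicate 4. AMT1.3 and GDH1 (0.73) were the 2 called of 16 nitrogen uptake and assimilation genes, also adjusted over the list alone (camera adjusted p = 0.00621, and adjusted p = 0.16 with an estimated correlation). The genes that fell were SFERH-2 (-1.03 ± 0.23, adjusted p = 0.0163), GSTU26 (-0.91 ± 0.18, adjusted p = 0.00513), GSTL3 (-0.72 ± 0.14, adjusted p = 0.00513), the aldehyde dehydrogenase ALDH3H1 (-0.61 ± 0.11, adjusted p = 0.00192) and GSTL7 (-0.56 ± 0.13, adjusted p = 0.0215). With those 3, 3 of 34 glutathione S-transferases were lower. None of the 42 WRKY factors was called by limma (2 lower at an unadjusted p under 0.05), with a median of -0.30 (camera adjusted p = 0.0291, and adjusted p = 0.749 with an estimated correlation). CKX3 was not called without inoculated replicate 3 (2.06, adjusted p = 0.0521), and GSTL7 and SFERH-2 were called in 3 of 8 fits with 1 array left out. The 140 probe sets called were 115 higher and 25 lower, against 1756 higher and 1372 lower at an unadjusted p under 0.05. Fitted to the 18 h groups alone, the count was 506.

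At 24 h nearly all called probe sets were higher in inoculated cells (n = 3 per group). N-26 was 272-fold higher (8.09 ± 0.35, adjusted p = 5.99e-18), N-36A 88.4-fold (6.47 ± 0.54, adjusted p = 2.11e-10), ENOD55-2 57.8-fold (5.85 ± 0.44, adjusted p = 1.66e-11), ENOD55-1 53.7-fold (5.75 ± 0.97, adjusted p = 0.000728) and ENOD40B 48.9-fold (5.61 ± 0.45, adjusted p = 9.9e-11). MYB127 rose 12.6-fold (3.65 ± 0.35), N-21 8.76-fold (3.13 ± 0.35, and 2.52 to 3.63 with 1 array left out) and GA2OX8 8.60-fold (3.10 ± 0.53). N-70 was higher by 2.57 ± 0.38 with both means under the floor. PEPC7, a phosphoenolpyruvate carboxylase, rose 2.45-fold (1.29 ± 0.28, adjusted p = 0.0294), a call made in 1 of 6 fits with 1 array left out (adjusted p up to 0.329). Among the 12 nodulins, 7 were higher and 0 lower (7 higher and 1 lower adjusted over the list alone), with an adjusted p of 1.14e-08 with an estimated correlation. AMT1.3 and HS1pro1, higher at the early times, were not among the called probe sets.

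None of the 34 glutathione S-transferases was called by limma at 24 h (5 lower at an unadjusted p under 0.05), and their median was -0.41 (camera adjusted p = 6.04e-08, and adjusted p = 0.47 with an estimated correlation). GST3 had -1.28 ± 0.46 and was called with the block alone (adjusted p = 0.00149). The lignin gene CCR (1.40 ± 0.45, adjusted p = 0.0055 with the block) and CYP82A4 (1.22 ± 0.33, adjusted p = 0.0112 with the block) were likewise called with the block alone. GST3 and CCR were called in 2 of the 3 block fits with a pair left out and CYP82A4 in 0. Isoflavonoid and phenylpropanoid genes had a median of 0.18 with none of 35 called by limma with or without the block (4 higher and 1 lower at an unadjusted p under 0.05; 2 higher adjusted over the list alone; camera adjusted p = 0.0426, and adjusted p = 0.749 with an estimated correlation). The 31 seed storage and maturation markers had a median of -0.43, and of 0.07 without inoculated replicate 3 (camera adjusted p = 0.0256, and adjusted p = 0.863 with an estimated correlation), and none was called by limma or reached an unadjusted p under 0.05. The 55 called probe sets were 54 higher and 1 lower, against 436 higher and 187 lower at an unadjusted p under 0.05. With the block the count was 122 (110 higher and 12 lower), and 59 (59 higher and 0 lower) with the block but without the pair numbered 3.

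At 36 h 7 of the 10 called genes that carry a symbol were nodulins (n = 3 per group). N-26 was 149-fold higher (7.22 ± 0.35, adjusted p = 2.01e-16), N-36A 81.6-fold (6.35 ± 0.54, adjusted p = 4.16e-10), ENOD40B 43.2-fold (5.43 ± 0.45, adjusted p = 2.76e-10), ENOD55-2 40.3-fold (5.33 ± 0.44, adjusted p = 2.26e-10) and ENOD55-1 34.2-fold (5.10 ± 0.97, adjusted p = 0.00529). GA2OX8 (3.30 ± 0.53), N-21 (2.74 ± 0.35), MYB127 (2.60 ± 0.35), CKX3 (2.45 ± 0.53) and N-70 (2.1 ± 0.38) rose too. With 1 array left out, CKX3 was called in 2 of 6 fits and ENOD55-1 (4.29 to 6.25) in 3, and N-70 was not called without inoculated replicate 1 (1.62, adjusted p = 0.101). Of the 12 nodulins, 7 were higher and 0 lower (9 higher adjusted over the list alone), with an adjusted p of 3.71e-08 with an estimated correlation.

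With the block alone, the chalcone isomerase CHI1B1 (2.38 ± 1.30, adjusted p = 0.00996 with the block) and WRKY34 (1.83 ± 0.65, adjusted p = 0.00087 with the block) were called higher at 36 h. The SEs in this paragraph are those of the fit without the block. Lower with the block alone were YABBY12 (-1.70 ± 0.70, adjusted p = 0.0127 with the block), F6H1, of the isoflavonoid and phenylpropanoid list (-1.49 ± 0.42, adjusted p = 0.0129 with the block), and the calmodulin SCAM-5 (-1.38 ± 0.71, adjusted p = 0.0103 with the block). Of the 3 block fits with a pair left out, WRKY34 was called in 3, CHI1B1 (1.9 to 3.18), YABBY12 and SCAM-5 in 2 and F6H1 in 1. With 1 array left out, without the block, CHI1B1 ran from 0.76 to 4.37, WRKY34 from 1.14 to 2.69, YABBY12 from -2.48 to -0.92, F6H1 from -2.12 to -1.12 and SCAM-5 from -2.29 to -0.69. Isoflavonoid and phenylpropanoid genes had a median of 0.26 with none of 35 called by limma without the block and F6H1 with it (5 higher and 2 lower at an unadjusted p under 0.05; 3 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.0061, and adjusted p = 0.587 with an estimated correlation). The list counts its own members alone, each by 1 probe set that need not be the one named above. Glutathione S-transferases had a median of -0.25 with none of 34 called by limma without the block (5 lower at an unadjusted p under 0.05; camera adjusted p = 5.03e-05, and adjusted p = 0.691 with an estimated correlation). With the block 3 were lower, among them GST3 (-1.07 ± 0.46, adjusted p = 0.0102 with the block) and GSTU26 (-0.73 ± 0.21, adjusted p = 0.0103 with the block), both called in 2 of the 3 fits with a pair left out. The 11 green tissue markers had a median of -0.53 with none called (1 lower at an unadjusted p under 0.05; camera adjusted p = 0.0319, and adjusted p = 0.749 with an estimated correlation). The 53 probe sets called by limma were 53 higher and 0 lower, against 644 higher and 527 lower at an unadjusted p under 0.05. With the block 347 were called (228 higher and 119 lower, and 87 to 1004 with a pair left out), and without mock replicate 3 and no block the count was 86.

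At 48 h the nodulin changes were smaller than at 36 h for each of those named (n = 3 per group). N-26 was 71.1-fold higher (6.15 ± 0.35, adjusted p = 2.62e-14), ENOD40B 33.9-fold (5.08 ± 0.45, adjusted p = 1.64e-09), N-36A 29.3-fold (4.87 ± 0.54, adjusted p = 2.57e-07) and ENOD55-2 14.7-fold (3.88 ± 0.44, adjusted p = 4.39e-07). ENOD55-1 had 3.90 ± 0.97 (2.86 to 4.69 with 1 array left out) and was called with the block alone (adjusted p = 0.148 without it and 0.00461 with the block). CKX3 rose 5.61-fold (2.49 ± 0.53, adjusted p = 0.0278), MYB127 5.01-fold (2.32 ± 0.35, adjusted p = 0.000167), N-21 4.77-fold (2.26 ± 0.35, adjusted p = 0.000255) and PEPC7 2.41-fold (1.27 ± 0.28, adjusted p = 0.0498). F6H1 was 3.91-fold lower (-1.97 ± 0.42, adjusted p = 0.0274). PEPC7 was called in 0 of the 6 fits with 1 array left out (adjusted p up to 0.618), F6H1 in 2 and CKX3 (1.73 to 2.87) in 3. ENOD55-1 was called in 2 of the 3 block fits with a pair left out. Of the 12 nodulins, 5 were higher and 0 lower (8 higher adjusted over the list alone and 6 with the block), with an adjusted p of 3.64e-07 with an estimated correlation.

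The 10 calcium signalling genes had a median of -0.28 at 48 h with none called by limma without the block and 1 lower with it (2 lower at an unadjusted p under 0.05; camera adjusted p = 0.014, and adjusted p = 0.47 with an estimated correlation). The list counts 1 probe set per gene, which need not be the one named here. Of the named calmodulin probe sets, that of SCAM-4 had -1.12 ± 0.33 (adjusted p = 0.0263 with the block) and that of SCAM-1 -0.99 ± 0.32 (adjusted p = 0.0123 with the block). Each was called in 1 of the 3 fits with a pair left out. Aquaporins had a camera adjusted p of 0.0429 at 24 h, 0.0442 at 36 h and 0.0429 at 48 h, and of 0.691 at each of these times with an estimated correlation. N-26 was the called member of the 22 at each of them, also adjusted over the list alone, and at 48 h the list's median (-0.05, and 0.02 with each array centred on its median) and mean (0.19) differed in sign. The 42 called probe sets were 38 higher and 4 lower, whereas 365 were higher and 742 lower at an unadjusted p under 0.05. With the block 193 were called, 102 higher and 91 lower. That balance depends on single pairs, with 42 and 33 without pair 1, 43 and 5 without pair 2 and 344 and 566 without pair 3.

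Averaged over the 6 times, N-26 was 180-fold higher (7.49 ± 0.13), N-36A 52.3-fold (5.71 ± 0.21), ENOD40B 47.6-fold (5.57 ± 0.17), ENOD55-1 36.1-fold (5.17 ± 0.37) and ENOD55-2 18.9-fold (4.24 ± 0.17). GA2OX8 (3.23 ± 0.20), MYB127 (2.77 ± 0.14) and HS1pro1 (2.18 ± 0.25) also rose, with adjusted p up to 1.35e-07. The named genes that fell were the aquaporin PIP2-8 (-1.33 ± 0.38, adjusted p = 0.0485), WRKY37 (-1.20 ± 0.34, adjusted p = 0.0487), PM31 (-0.89 ± 0.24, adjusted p = 0.0317), BFT (-0.88 ± 0.22, adjusted p = 0.0213), SSH2 (-0.83 ± 0.19, adjusted p = 0.0091) and WRKY30 (-0.78 ± 0.19, adjusted p = 0.0131). Of the 42 fits with 1 array left out, WRKY37 was called in 9, PIP2-8 in 11 and PM31 in 28. Of the 12 nodulins 8 were higher and 1 lower, the latter SAT1 (-0.41, adjusted p = 0.0031; 2 lower adjusted over the list alone). Of the 34 glutathione S-transferases 6 were lower (10 adjusted over the list alone and 14 with the block). They had a camera adjusted p of 6.92e-07, and an adjusted p of 0.288 with an estimated correlation. GSTU27 (-0.64), GSTU26 (-0.64), GST3 (-0.66) and GSTL3 (-0.29) were among them. Nitrogen uptake genes had 2 of 16 higher (camera adjusted p = 0.0437), and calcium signalling genes 1 of 10 lower, SCAM-4 with -0.72 (camera adjusted p = 0.0124). Both had an adjusted p of 0.288 with an estimated correlation. In all 698 probe sets were called, 331 higher and 367 lower, against 3368 with the block, which also pairs the 18 h arrays (1470 higher and 1898 lower), and 1411 without mock 12 h replicate 3.

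The treatment effect differed between times for 64 probe sets by the moderated F test. Among named genes, ENOD55-2 (adjusted p = 5.75e-07), N-26 (adjusted p = 5.04e-06), N-21 (adjusted p = 1.71e-05) and N-70 (adjusted p = 0.000106) had the smallest adjusted p. NOD33 (adjusted p = 0.000705) had -0.84 at 12 h and 0.61 at 36 h, where it was not called (adjusted p = 0.575). With the block 5173 probe sets differed between times. Without the block the count was 42 without mock 12 h replicate 2, 1449 without mock 12 h replicate 3, 207 without inoculated 12 h replicate 4 and 41 without inoculated 18 h replicate 4.

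A set of 22 probe sets was called higher at each of the 6 times, and 0 were called lower at each (32 and 0 with the block). Of the 22, 4 carry a gene symbol, N-26, N-36A, ENOD40B and MYB127. The strongest, chosen after its values were seen, was a probe set for which the annotation lists no gene, with log2 changes of 9.07 at 6 h, 11.5 at 12 h and 9.83 at 48 h (adjusted p = 7.45e-23, 3.16e-26 and 5.56e-22). Calls overlapped between times beyond the number that independent lists would share. Higher at both 12 and 18 h were 103 probe sets against 3.85, at both 18 and 24 h 52 against 0.242, and at both 24 and 36 h 48 against 0.111. Lower at both 12 and 18 h were 23 against 0.602. Without the block 0 probe sets were called in opposite directions at any pair of times. With the block, among the times whose numbers pair the arrays, 34 were at 12 and 36 h, 24 at 12 and 48 h, 5 at 6 and 12 h, 2 at 6 and 24 h and 2 at 12 and 24 h. Across all tested probe sets, which are not independent replicates, the log2 changes correlated at 6 and 12 h (r = 0.776), 12 and 18 h (r = 0.887) and 24 and 36 h (r = 0.714), but little at 18 and 24 h (r = 0.0752). The last pair lies in different sets of arrays.

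Mock cells were compared over time to show what changed without bacteria, first 18 h against 6 h (n = 4 per group). Named genes that rose included the protease genes CYSP1 (gene 548011) 16.1-fold (4.01 ± 0.34, adjusted p = 6.55e-09), CYSP2 (gene 547487) 13.8-fold (3.79 ± 0.40, adjusted p = 4.77e-07) and the vacuolar processing enzyme VPE2 6.80-fold (2.76 ± 0.34, adjusted p = 5.8e-06). MYB134 (2.82 ± 0.39), WNK5 (2.73 ± 0.59), MYB186 (2.28 ± 0.38), the galactinol synthase GOLS (2.15 ± 0.43) and WRKY12 (1.99 ± 0.43) rose as well. Genes lower at 18 h were the metalloproteinase MMP2 (-2.35 ± 0.32, adjusted p = 3.17e-05), 4CL3 (-2.09 ± 0.54, adjusted p = 0.0446), the glyceollin gene G4DT (-1.98 ± 0.48, adjusted p = 0.0269), GASA21 (-1.73 ± 0.29, adjusted p = 0.000564), AMT1.3 (-1.69 ± 0.35, adjusted p = 0.00729) and NAC19 (-1.52 ± 0.39, adjusted p = 0.0361). Of the 8 fits with 1 array left out, 4CL3 was called in 1, G4DT and NAC19 in 3 and WRKY12 in 5. WNK5 was not called without mock 18 h replicate 4 (2.50, adjusted p = 0.0684). AMT1.3 thus had mock means of 5.33 at 6 h and 3.63 at 18 h, and inoculated means of 6.86 and 6.69. Of 31 seed storage and maturation markers none was called over all probe sets (3 higher and 15 lower at an unadjusted p under 0.05), but 13 were lower and 2 higher adjusted over the list alone. Their median was -1.32 (camera adjusted p = 2.3e-06, and adjusted p = 0.66 with an estimated correlation). The gibberellin and GASA list had a median of -0.56 with GASA21 called (camera adjusted p = 4.73e-05, and adjusted p = 0.66 with an estimated correlation). The 315 called probe sets were 241 higher and 74 lower. The count was 120 without mock 18 h replicate 4, whose median correlation with its group was 0.933, 197 without mock 6 h replicate 2, 165 without replicate 3 and 202 without replicate 4.

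Between 24 and 48 h, mock cells changed in some genes of green tissue and phloem (n = 3 per group), and neither list passed camera with an estimated correlation. CAB3 (gene 547862), a chlorophyll a/b-binding protein, was 65.3-fold lower at 48 h (-6.03 ± 1.08, adjusted p = 0.000403, and -7.83 to -4.44 with 1 array left out). Its other probe sets had -5.85, -4.09 and 1.36, all called. The related LHCP fell 31.8-fold (-4.99 ± 0.90, adjusted p = 0.000434), and GER10 (-5.53 ± 1.08), YABBY11 (-4.70 ± 0.87), GSTU3 (-4.21 ± 0.64) and SGlu11 (-3.79 ± 0.82) fell with adjusted p up to 0.00269. Of 11 green tissue markers 6 were lower, also adjusted over the list alone, among them PETC of the cytochrome complex (-3.52) and the Rubisco activase genes RCABETA (-3.29) and RCAALPHA (-2.97). PSAD (-0.08) and NDHK (0.00) were not called. The median was -2.58 (camera adjusted p = 1.64e-06, and adjusted p = 0.249 with an estimated correlation). The genes that rose most were GASA24 (3.88 ± 0.74, adjusted p = 0.000826), SEOC (3.26 ± 0.68, adjusted p = 0.00207), BZIP83 (3.13 ± 0.54, adjusted p = 0.000276) and GASA29 (3.12 ± 0.66, adjusted p = 0.00239), followed by NF-YA05 (2.78 ± 0.75), MYB145 (2.49 ± 0.58), the tonoplast channel TIP2;3 (2.07 ± 0.62) and SEOA (1.87 ± 0.56). With 1 array left out, LHCP ran from -6.23 to -4.14, GER10 from -6.29 to -4.93, GSTU3 from -4.81 to -3.86, SGlu11 from -4.54 to -3.21 and BZIP83 from 2.67 to 3.79, called in each of 6 fits. TIP2;3 and SEOA were called in 2 of the 6, NF-YA05 (2.16 to 3.35) in 3 and MYB145 (1.8 to 3.14) in 4. SEOC and SEOA encode sieve element occlusion proteins of the phloem.

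SEOC and SEOA were the 2 called of 5 phloem markers at 48 against 24 h in mock cells (3 adjusted over the list alone and 3 with the block; median 1.47; camera adjusted p = 0.0131, and adjusted p = 0.576 with an estimated correlation). Of 51 bZIP factors 3 rose, BZIP83, BZIP42 (1.85) and BZIP114 (1.5), also adjusted over the list alone, and 4 with the block (camera adjusted p = 0.00549, and adjusted p = 0.249 with an estimated correlation). Of 31 seed storage and maturation markers 3 fell, PM30 (-2.79), PM1 (-2.0) and PM22 (-1.87), with 4 lower adjusted over the list alone (camera adjusted p = 0.000956, and adjusted p = 0.842 with an estimated correlation). These 3 were not called with the block (adjusted p = 0.135, 0.0805 and 0.102), which called 1 other. In all 2132 probe sets were called, 1298 higher and 834 lower at 48 h, and with mock replicate number as a block 1626 (836 higher and 790 lower), of which 1084 were in both counts. The count was 1188 and 781 without 24 h replicates 1 and 3, and 979, 1002 and 3665 without 48 h replicates 1, 2 and 3.

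**Figure D3:**
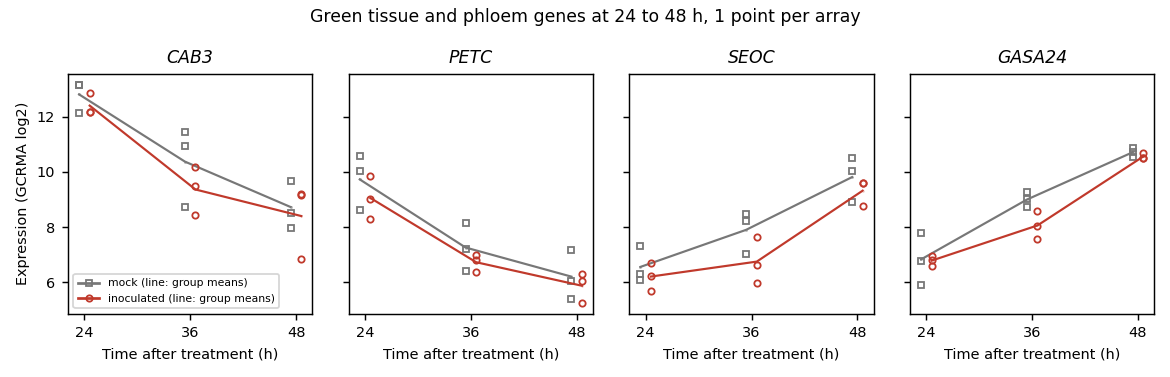
Expression (GCRMA log2, vertical axis) of CAB3 and PETC (green tissue) and SEOC and GASA24 (raised in mock cells at 48 h) against time after treatment (h, horizontal axis), with 1 point per array, squares for mock, circles for inoculated and lines through group means. CAB3 is drawn from the probe set used in the green tissue list, whose mock means were 12.8 at 24 h and 8.72 at 48 h and inoculated means 12.4 and 8.40.

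The remaining 13 of the 27 gene lists passed camera in none of the 9 contrasts. Protease inhibitors (6 genes; lowest adjusted p = 0.202), ERF and DREB factors (12; 0.103), peroxidases and antioxidant enzymes (16; 0.0839), cell wall genes (15; 0.094), auxin genes (8; 0.324) and lipoxygenase and jasmonate genes (18; 0.311) were among them. The others were phosphate genes (14; 0.55), iron and metal genes (9; 0.41), receptor-like kinases (14; 0.27), heat shock genes (14; 0.336), MYB factors (44; 0.0709), SWEET and sugar transport genes (8; 0.059) and 14-3-3 proteins (8; 0.668). Their medians lay between -0.57 and 0.94 over all contrasts. Nodulins and nodulation regulators were the 1 list of 27 that passed with an estimated correlation, and at 6 and 12 h they did not pass with the block as well.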

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

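Of the tests in this part, those of the replicate axis at 6 and 18 h, of green tissue carry-over, of the mock arrays alone and of a response that differs between the early and the late times were chosen after the result was seen. Among 128 groups of 4 values checked with Dixon's test, 10 held a value far from the other 3, and chance gives this in about 1 in 20 groups. By median correlation with the rest of their group, inoculated 6 h replicate 1 (0.891, against a mean of 0.974 for the others) and mock 18 h replicate 4 (0.933, against 0.979) lay low, and inoculated 18 h replicate 4 (0.984, against 0.979) lay high. HS1pro1 was 4.26 in inoculated 6 h replicate 1 against a mean of 7.37 in the others, and ENOD55-1 was 10.7 in inoculated 6 h replicate 3 against 9.57. MYB176 was 12.8 in inoculated 12 h replicate 4 against 12.5, N-36A was 6.27 in mock 12 h replicate 2 against 5.54, and PR1-1 was 4.69 in that array against 5.86. ENOD40B was 13.9 in inoculated 18 h replicate 3 against 13.8, and GSTL3 was 14.7 in mock 18 h replicate 4 against 14.5.

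For 10 of the 36 named probe sets tested, the treatment effect differed between times by limma's moderated F test. Their adjusted p were 5.75e-07 for ENOD55-2, 5.04e-06 for N-26, 1.71e-05 for N-21, 0.000106 for N-70, 0.000705 for NOD33, 0.0011 for N-36A, 0.00896 for ENOD40B, 0.00992 for PR1-1, 0.0153 for AMT1.3 and 0.0358 for MYB176. N-21 and N-70 went from -0.01 and 0.00 at 6 h to 2.99 and 3.84 at 18 h, whereas PR1-1 had 2.88 at 6 h and was not called from 18 h on. Of the 48 ribosomal RNA probe sets, which no comparison uses, 3 were called at 48 h, where their median change was 0.67 (-0.60 at 6 h).

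More probe sets were called at 12 h (1480) than at 18 h (140), and a single array that stands apart or p-values close to the threshold may account for it. Without replicate 4 of both mock groups, the SD of the log2 changes at 12 h was 1.19 times that at 18 h (1.23 with all arrays), between the values set beforehand for and against that array. The count at an unadjusted p under 0.05 moved 3.08-fold (2689 to 8295) when 1 array of the 12 h groups was left out, also between the values set beforehand. Both explanations stay open, as does a larger response at 12 h, which these tests do not part from them. The order of the counts also depends on how the spread is estimated. Fitted to the groups of each time alone, fewer probe sets were called at 12 h than at 18 h. Without mock 12 h replicate 4 the count at 12 h was 137.

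Log2 changes at 6 to 18 h correlated with each other (r = 0.887 at 12 and 18 h) and not with those at 24 to 48 h. The leading axis on which replicates differ at 6 to 18 h was given the sign that places inoculated arrays higher on average. With that sign the inoculated array scored above the mock array of its number in 11 of 12 pairs, those of 18 h included. This axis is argued against as the whole source at 12 and 18 h, because r there was still 0.815 after it was taken out. It held 57.9% of the squared change at 12 h, and as r fell from 0.776 to 0.614 at 6 and 12 h and from 0.685 to 0.497 at 6 and 18 h, it may be part of the source, and at 6 and 18 h how much stays open. For separate normalisation of the array sets, the Spearman correlation of the changes was taken among the 17963 probe sets above the floor in every group. It was -0.323 at 18 and 24 h (0.915 at 12 and 18 h, 0.711 at 24 and 36 h). Normalisation nearly keeps the ranks of levels within an array but not those of changes between groups, so this value cannot decide. A response that differs between the early and the late times may account for the r of 0.0752 at 18 and 24 h. It cannot be told apart from separate normalisation or another difference between the sets of arrays, since they part between these times.

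Green tissue markers were lower in mock 48 h than in mock 24 h cells (median log2 change -2.58). The arrays numbered 3, which stand apart at 24 to 48 h, are argued against by a median of -2.42 without them, and a difference in the mock arrays alone by a median of -1.89 between inoculated 48 h and inoculated 24 h. Carry-over of green tissue into the 24 h samples, which the root hair isolation should remove, may account for the pattern. It cannot be told apart from a change with seedling age, which was not tested, as 6 of the 11 markers were over 1 lower on the log2 scale, among them CAB3 (12.8 at 24 h and 8.72 at 48 h), while PSAD stayed high (13.6 and 13.5) and 3 markers with 24 h means under 10 changed by less than 0.5. In mock 48 h cells 10 of the 11 markers lay above the floor of 5.

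Other splits of the arrays were compared with the real split, by the number of probe sets called. At 18 h 1 of the 35 splits, the real one, called as many (140, with a highest other of 0), as did 1 of 35 for mock 18 h against 6 h (315 and 18). By these splits chance can be excluded for those 2 comparisons only as far as their arrays are not paired, and the shares are not adjusted over the comparisons split. At 6 h 1 of 35 called as many too (114 and 8). There the numbers pair the arrays and these splits leave the pairs aside, so they cannot exclude chance. At 12 h 2 of 35 called as many, so chance cannot be excluded. The split that swaps inoculated replicate 4 with mock replicate 3 called 6129 against 1480, which points to a structure of the samples. The 10 splits at 24 h (55 and a highest other of 11), 36 h (53 and 13953), 48 h (42 and 10191) and for mock 48 h against 24 h (2132 and 113) are too few for a share under 0.05. As many were called by 1, 2, 2 and 1 of them. The other splits that called most at 36 and 48 h set both arrays numbered 3 against both numbered 2, which points to a structure of the samples by replicate number. Where the numbers pair the arrays, the other splits that part each pair called 0 at 6, 12, 24, 36 and 48 h, and with the block at most 3. These splits, 8 at 6 and 12 h and 4 at the later times with the real one, are too few for a share under 0.05. Averaged over times, 5 of 100 drawn splits called as many as the 698 (highest other 10791), and for the difference between times 12 of 100 called as many as the 64 (highest other 9534), so chance cannot be excluded and the samples hold a structure besides the treatment. With the block, swaps within pairs gave 1 of 100 for both (3368 against 1060, and 5173 against 3569). The swaps also treat the 18 h arrays as pairs, though not every pair there deviated together, and for the average they exclude chance only as far as that pairing holds. They remove an effect common to all times as well, so for the difference between times they cannot decide.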

How the results depend on the processing

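The added fits (array weights gene by gene, each set of arrays fitted apart, without the arrays that stand apart, with and without the block, and without the arrays numbered 3) were chosen after seeing the data. With 3 or 4 arrays per group and residuals that share a replicate structure, the counts depend on how the spread is estimated. Values under the floor of 5 rest on the background model, and no signal over background is given per probe set. The test of other organisms' probe sets was not run. The stricter floor, leaving out probe sets that can cross-hybridise and no intensity trend kept each count within 1.5 times, as did centring, which changed the mock 48 h against 24 h split from 1298 higher and 834 lower to 961 and 940. Of the 220 values of named genes, 198 or more kept direction and side of the threshold with no filter, quantile normalisation, centring or no trend, 165 with the block (55 more were called) and 130 of 206 with the compared groups alone (75 fewer called). For the changed results below the cause was not tested, except that no filter tests more probe sets. The groups compared alone leave fewer arrays to estimate the spread and use the spread of those groups only. With them the counts rose in some comparisons and fell in others, so fewer arrays alone cannot account for the changes.

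Without the filter 926 probe sets were called at 12 h. With quantile normalisation 2306 were called at 12 h and 1383 for mock 48 h against 24 h. With array weights, whose default estimator stopped before convergence (weights 0.0267 to 2310), the counts were 4255 at 6 h, 11104 at 12 h, 4052 at 18 h, 13467 at 24 h, 18743 at 36 h, 20332 at 48 h, 10725 averaged, 23924 for the difference between times, 5061 for mock 18 h against 6 h and 20243 for mock 48 h against 24 h. With weights estimated gene by gene (0.0779 to 9.96) they were 6741, 10174, 2874, 1685, 10967, 10068, 4910, 18500, 6144 and 14019 in that order.

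With the replicate block the counts were 563 at 6 h, 8072 at 12 h, 2169 at 18 h (1133 higher and 1036 lower), 122 at 24 h, 347 at 36 h, 193 at 48 h, 3368 averaged, 5173 for the difference between times and 1200 for mock 18 h against 6 h. At 18 h and for mock 18 h against 6 h the numbers do not pair all arrays: at 18 h inoculated and mock replicate 3 deviated with r = -0.168, and replicate 3 of mock 6 and 18 h with r = -0.391. With the replicate block but without the 3 pairs that hold an array standing apart, the counts were 678, 5499, 276, 145, 424 and 519 at the 6 times, 2798 averaged and 3564 for the difference between times.

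Fitted to the compared groups alone, the counts were 56 at 6 h, 76 at 12 h, 506 at 18 h, 5 at 36 h, 5 at 48 h, 1237 for mock 18 h against 6 h and 62 for mock 48 h against 24 h. With each set of arrays fitted apart they were 3346 at 12 h, 241 at 18 h, 1132 for mock 18 h against 6 h and 654 for mock 48 h against 24 h. Without the 3 arrays that stand apart (inoculated 6 h replicate 1, mock 12 h replicate 4 and mock 18 h replicate 4) they were 74 at 6 h, 154 at 12 h and 171 for mock 18 h against 6 h. Mock 12 h replicate 4 lay far out on the leading axis on which replicates differ at 6 to 18 h (score -128). By median correlation with its group (0.948) it did not lie low, as mock 12 h replicate 3 had 0.938. Without the arrays numbered 3 at 24 to 48 h, 97 were called at 36 h and 4256 for mock 48 h against 24 h.

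With 1 array left out in turn, the counts ran from 61 to 117 at 6 h, 137 to 5140 at 12 h, 99 to 134 at 18 h, 46 to 56 at 24 h, 44 to 86 at 36 h and 31 to 55 at 48 h. They ran from 533 to 1411 averaged, 41 to 1449 for the difference between times, 120 to 286 for mock 18 h against 6 h and 781 to 3665 for mock 48 h against 24 h. Of the named genes called at 6, 12, 18, 24, 36 and 48 h, 8 of 15, 14 of 40, 14 of 17, 9 of 10, 7 of 10 and 6 of 9 were called whichever array was left out.

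Some values changed sign. The aquaporin median at 48 h was 0.0174 with each array centred. The gibberellin and GASA median at 18 h was -0.00731 with array weights, -0.0407 with weights gene by gene and -0.00565 without the 3 arrays that stand apart. PR-10 had 0.43 at 48 h with array weights. With 1 array left out, aquaporin medians ran from -0.0335 to 0.212 at 24 h, -0.0907 to 0.475 at 36 h and -0.413 to 0.274 at 48 h. In the same way the gibberellin and GASA median ran from -0.00565 to 0.467 at 18 h and the seed storage median from -0.806 to 0.0739 at 24 h.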

Other observations

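The comparison of inoculated 48 h with inoculated 24 h cells was added after seeing the data, as was the choice of ITPK4 for this part, so the tests here that use them were chosen only after results were seen. ITPK4 was called higher at 6 h (1.2, adjusted p = 0.0175), 12 h (1.95, adjusted p = 6.17e-06) and 18 h (1.35, adjusted p = 0.00254). At 24, 36 and 48 h its log2 changes were 1.16, 0.95 and 0.99 (adjusted p = 0.155, 0.551 and 0.478), and with the replicate block it was called at these times too, in 2, 2 and 1 of the 3 fits with a pair left out. Besides the 22 probe sets higher at each time, 19 were called higher at 5 times, 10 at 4 and 782 at a single time. Of the probe sets called lower, 596 were called at a single time, 32 at 2 and 1 at 3.

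Inoculated cells at 48 h against 24 h (n = 3 per group) gave 1937 called probe sets, 1042 higher and 895 lower at 48 h. Of these, 1159 were called by limma in the same direction in mock cells and 0 in the opposite direction, and across all tested probe sets, which are not independent replicates, the log2 changes of inoculated and mock cells correlated at r = 0.878. Same-numbered arrays of the 2 arms share deviations at both times, so r and the shared calls are not free of that structure. Taken array by array, the 48 h minus 24 h differences of the arms correlated at r of 0.757 to 0.816 for the same replicate number. They correlated at 0.258 to 0.87 (median 0.487) for the 6 combinations of other numbers. In inoculated cells CAB3 fell by 4.0, PETC by 3.18, RCAALPHA by 2.35 and ELIP by 1.89, against changes of -4.09, -3.52, -2.97 and -2.58 in mock cells. PSAD (0.11) and RCA11 (0.10) had small changes in inoculated cells, and NDHK had 1.13.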
